A study of Mus musculus with 6 samples.

How the data were processed

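RNA-seq gene counts were analysed for 6 libraries of mouse cells collected on day 4 of mesendoderm differentiation, 3 from wild-type (WT) E14 embryonic stem cells and 3 from E14 cells carrying Cnot3-T292A/S294A, a mutation that replaces a threonine and a serine of the CNOT3 protein with alanine. Per the labels' protocols, RNA was taken from the same counted number of cells in every sample, 2 µl of an ERCC spike-in mix diluted 1 in 10 was added to every sample, and 500 ng of RNA entered a stranded polyA library preparation. ERCC spike-ins are synthetic transcripts of known composition, so their share of a library depends on how much cellular RNA each added volume met.

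The deposited values are raw read counts, one table for genes and one for ERCC species, with no normalization and no pooling of replicates. Per the submitters' processing notes, the tools were CASAVA 1.8.4, TopHat2 2.0.11 and featureCounts, with the mouse builds mm9 and NCBIM37. The featureCounts version, the annotation release and the strand setting are not given in the sources used here, so counts of overlapping or antisense genes, and of genes with near-identical copies, are uncertain. The gene table held 37991 Ensembl gene identifiers, of which 22919 had a count above 0 in any library. Symbols came from the GENCODE M21 annotation (assembly GRCm38), which matched 32919 identifiers carrying 99.47% of the counts. That assembly is not the one the counts were made on, so it served only for names, gene length, GC content and the order of neighbouring genes, and no coordinates are printed. The ERCC table held 92 species, 59 of them with a count above 0.

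Gene counts per library were 17499283, 16767547 and 17358452 for WT replicates 1 to 3 and 17705227, 19447549 and 18157508 for mutant replicates 1 to 3. Levels are given as CPM, the usual scaling of counts to library size. A floor of 3 counts corresponds to 0.154 to 0.179 CPM over the libraries. ERCC counts ranged from 4828 to 14374 per library. Replicates of a group differed from each other by more than sampling noise, with chi-square per degree of freedom from 8.20 to 50.3, so no library was treated as a duplicate. The labels number the replicates but do not say whether they were separate cultures, so p-values measure only the spread between these samples, which can be technical.

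The main comparison, mutant minus WT, used edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM library sizes, the quasi-likelihood F test at its default settings, and Benjamini-Hochberg adjustment over the 14161 genes left, calling genes at an adjusted p under 0.05. CPM values use TMM library sizes, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. DESeq2 1.42.0 (Wald test, genes without an adjusted p left out) was the other count test. Fixed lists with at least 3 tested members, 38 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry. Each list also has a count of members past 0.05 when edgeR p-values were adjusted over the list alone. A principal component analysis used log2 CPM with a prior count of 2. The ERCC share of all counts was compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3, and single ERCC species were compared with edgeR using ERCC totals as library sizes, as a negative control.

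The tests, the lists, most alternatives and the rule for named genes were set before the data were examined. The alternatives were DESeq2 size factors, total counts or ERCC totals in place of TMM, no filter or a mean CPM of at least 1, DESeq2 or limma-voom, the replicate number as a block, an adjusted p under 0.01, a fold of at least 2, and leaving out each library. An adjusted p under 0.1, edgeR with bias-adjusted deviances, and DESeq2 without each library were added after seeing the data. Leaving out a library reran the filter, so the tested members of a list could change. The rule named Cnot3 and the other CCR4-NOT subunits, the 8 largest rises and falls among called genes with a mean CPM of at least 5 and no overlap between groups (without predicted, clone-named or pseudogene symbols), and from each described list up to 4 called members or, where none was called, the 2 with the highest mean CPM. Because edgeR called 1 gene, the same rule for rises and falls was applied to the DESeq2 calls after the data were seen, and further list members are said below to be chosen after their values were seen. From the genes so named, 1 is left out and not reported here.

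Among the 38 lists, 10 members had no identifier with that symbol in the table and were not used here. Of 629 fixed members 551 were tested, and counts below are of tested members. The filter can keep a gene through its level in 1 group alone, while members low in both groups drop out. The lists cover CCR4-NOT subunits, other mRNA decay factors, pluripotency, germ layers and extraembryonic lineages, other cell types, signalling targets, cell cycle, stress, metabolism, imprinted genes and Y-linked genes. The edgeR and DESeq2 steps were tested on simulated counts drawn from the means, dispersions and library sizes of these 6 libraries over 14161 genes. The 200 changed genes were taken from those with a mean CPM above 5. Genes were drawn independently, without the spread that many genes share within groups here. The recovery below therefore does not give the power of the tests in these data. At an adjusted p under 0.05, edgeR recovered 29.9% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. DESeq2 recovered 58.2%, 94.0% and 100% (39, 63 and 66 genes), with 28 false calls. That share of false calls was above the nominal 0.05, so DESeq2 calls may hold more false positives than the threshold states. In the same simulation, which had no correlation between genes, a DNA replication list raised 1.3-fold was called by camera, and 0 of the other lists were. With an estimated correlation that list was not called (camera adjusted p = 0.0518). In a further run with dispersions scaled by 0.1, edgeR made 22 false calls and DESeq2 17, so false calls were not particular to DESeq2. In that run the list was called with an estimated correlation (camera adjusted p = 0.00991).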

Results

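Gene expression was measured by polyA RNA-seq in mouse cells driven towards mesendoderm, the common precursor of mesoderm and endoderm, by BMP4 and FGF2 in serum-free medium for 4 days. The cells came from E14 mouse embryonic stem cells, either WT (3 libraries) or with the Cnot3-T292A/S294A mutation (3 libraries, called mutant below). CNOT3 is a subunit of CCR4-NOT, the complex that shortens mRNA poly(A) tails, and per the series title the study concerns its phosphorylation by the mitotic kinase Aurora B. The libraries held 16767547 to 19447549 gene counts each. The question addressed by the comparison is how the transcriptome of differentiating cells differs when these CNOT3 sites are replaced.

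Cnot3 mRNA (ENSMUSG00000035632), the edited gene, was at 103, 87.4 and 95.6 CPM in WT replicates 1 to 3 and at 62.4, 59.2 and 57.1 CPM in mutant replicates 1 to 3. The group means were 95.3 ± 7.65 and 59.6 ± 2.68 CPM (SD, n = 3), a log2 fold change of −0.68 (SE 0.09). This difference did not pass the edgeR quasi-likelihood test after adjustment over all genes (adjusted p = 0.0931) and passed DESeq2 (adjusted p = 1.65e-05). The mutation is a substitution within the coding sequence, so the mRNA level does not check the genotype labels. Of the 11 CCR4-NOT subunits, Cnot3 was the 1 past the threshold when edgeR p-values were adjusted over the list alone, and the 1 called by DESeq2. The others had smaller edgeR log2 fold changes, from −0.26 for Cnot6l (SE 0.15) through −0.17 for Cnot8, −0.10 for Cnot1, −0.07 for Cnot4 and −0.01 for Cnot7 to 0.11 for Cnot2, 0.18 for Cnot10, 0.24 for Cnot6, 0.26 for Cnot11 and 0.33 for Cnot9 (SE 0.13). With ERCC totals as library sizes the negative values of Cnot1, Cnot4, Cnot6l, Cnot7 and Cnot8 turned positive, and Cnot3 stayed at −0.13. As a list the subunits had a median of −0.01 and were not called by camera (adjusted p = 0.908).

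Over all genes, 1 of 14161 passed the edgeR threshold. It was Nudcd3 (ENSMUSG00000053838), which encodes a NudC-domain protein and fell from 193 ± 1.34 to 87.6 ± 4.97 CPM (SD, n = 3). Its log2 fold change was −1.14 (SE 0.08, edgeR adjusted p = 0.00983), with 194, 194 and 192 CPM in the WT libraries and 84.6, 93.4 and 84.9 CPM in the mutant libraries. With ERCC totals as library sizes its value was −0.55 (edgeR adjusted p = 0.656). The call was also lost without WT replicate 3 or without any 1 of the mutant replicates, with edgeR log2 fold changes from −1.19 to −1.10 in those fits.

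The single call stood beside a broad shift in the unadjusted values. At an unadjusted p under 0.05 edgeR gave 3910 genes, 27.6% of those tested, with 1879 higher and 2031 lower in mutant cells. In 2323 genes all mutant libraries lay above all WT libraries and in 2317 all lay below, together 32.8% of genes. Chance gives 10% on average over all splits of the libraries into 3 and 3. Because many genes moved together, a single split can exceed that average by chance. The share was not computed for the other splits. The next smallest edgeR adjusted p was 0.0862, and 840 genes lay under 0.1, a threshold chosen after seeing the data. DESeq2 called 1667 genes, 733 higher and 934 lower. The edgeR count rose to 2796 without WT replicate 1 and was 0 without WT replicate 3 or any 1 mutant replicate. The DESeq2 count ranged from 221 without mutant replicate 1 to 3386 without WT replicate 1. Scaling by ERCC totals moved the median log2 fold change of all genes to 0.57 and gave 113 edgeR calls, 113 higher and 0 lower, against 0 higher and 1 lower with TMM. Directions below are relative to the TMM scale.

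**Figure D1:**
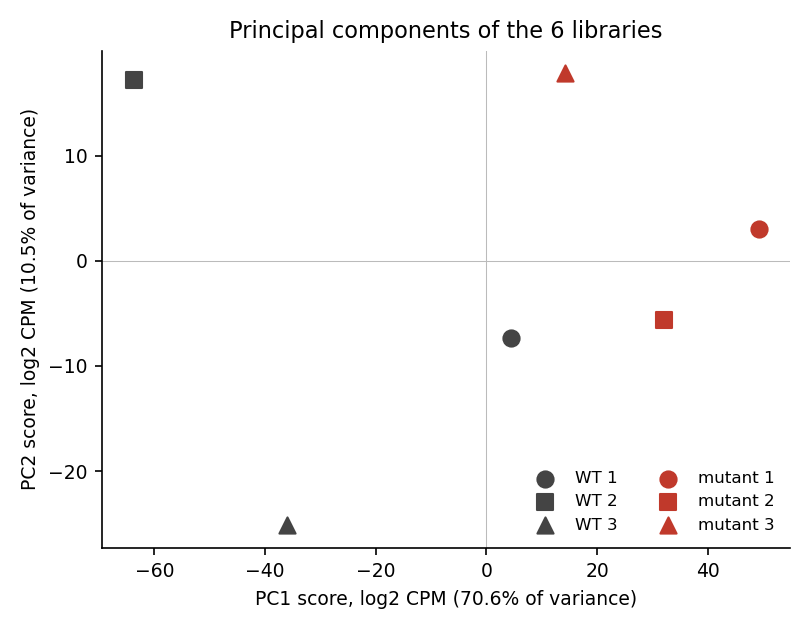
Scores of the 6 libraries on principal components PC1 and PC2 of log2 CPM, with WT in grey, mutant in red and the replicate number as the marker shape. The mutant libraries sit at 14.2 to 49.2 on PC1 and the WT libraries at −63.7 to 4.36, with WT replicate 1 nearest to the mutant group.

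The first principal component held 70.6% of the variance. WT replicates 1 to 3 scored 4.36, −63.7 and −36.1 on it, and mutant replicates 1 to 3 scored 49.2, 32.0 and 14.2. The group difference of 63.6 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. WT replicate 1 thus lay nearer to mutant replicate 3 than to either other WT library, and the spread along this component within WT (SD 34.2) was larger than within mutant (SD 17.5).

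Markers of the primitive streak, where mesendoderm forms, had higher means in mutant libraries. T, the mesoderm transcription factor Brachyury, was at 75.5, 6.89 and 9.61 CPM in WT replicates 1 to 3 and at 245, 157 and 90.7 CPM in mutant replicates 1 to 3, a 5.33-fold difference. Tdgf1, a NODAL co-receptor, averaged 75.8 ± 76.1 CPM in WT and 231 ± 94.2 CPM in mutant (SD, n = 3). Mixl1 and Mesp1, mesendoderm and early mesoderm transcription factors chosen after their values were seen, averaged 2.96 and 2.61 CPM in WT against 30.9 and 20.6 CPM in mutant. None of these 4 genes passed edgeR or DESeq2 (adjusted p from 0.12 to 0.184 and from 0.0837 to 0.247). Fst, which encodes the activin antagonist follistatin, was called by DESeq2 at a log2 fold change of 2.60 (adjusted p = 0.00869). Of 17 tested members of the primitive streak and mesendoderm list, 0 passed edgeR over all genes, 2 were higher when adjusted over the list alone, and 2 were higher by DESeq2. The list median was 1.85, and camera called the list higher (adjusted p = 6.22e-08). Without WT replicate 1 the median was 3.41, over 18 tested members. With all libraries the call was lost with an estimated correlation (adjusted p = 0.423). The list score of a library is the median over members of log2 CPM minus the gene's mean over all libraries. It overlapped between the groups, at 0.539 in WT replicate 1 and 0.415 in mutant replicate 3.

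**Figure D2:**
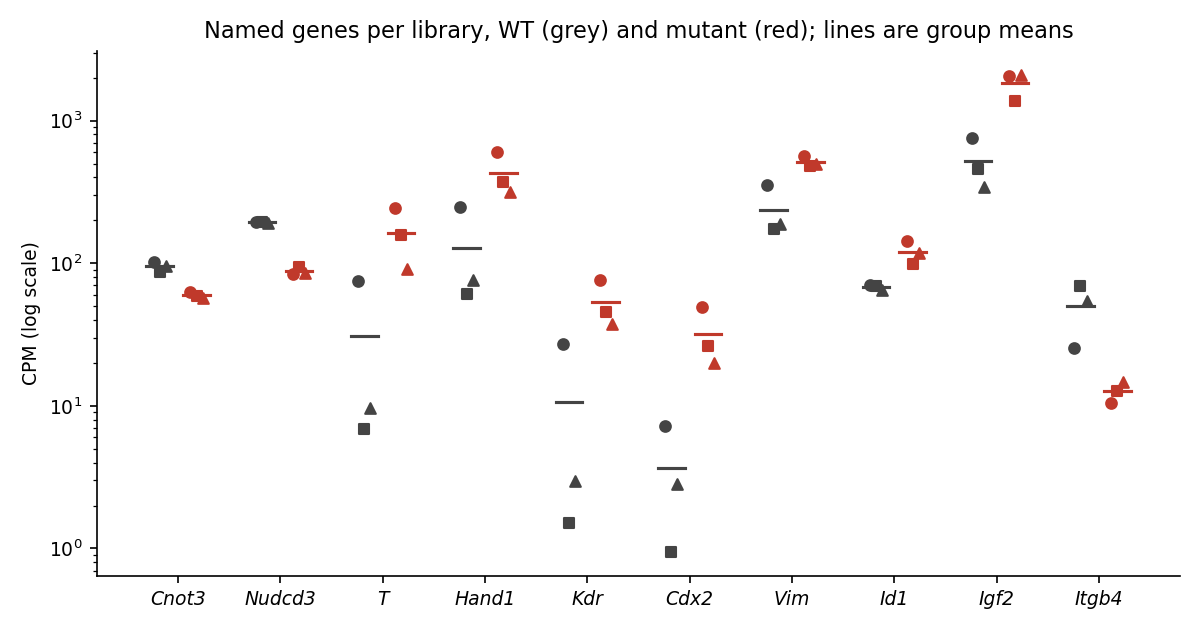
CPM per library on a log scale for 10 named genes, WT in grey and mutant in red, with circles, squares and triangles for replicates 1, 2 and 3 and lines at the group means. Cnot3 and Nudcd3 have tight groups, while for T, Kdr and Cdx2 the first WT library lies between the other WT libraries and the mutant libraries.

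Genes of lateral plate, cardiac and blood-forming mesoderm were higher in mutant cells, in both lists for most tested members. Hand1, a transcription factor of lateral mesoderm, was at 247, 61.0 and 76.3 CPM in WT and 599, 374 and 317 CPM in mutant libraries, and did not pass either test over all genes (edgeR adjusted p = 0.109, DESeq2 adjusted p = 0.0924). Bmp4, which encodes a ligand of the kind added to the medium, went from 50.4 ± 22.1 to 112 ± 21.7 CPM (SD, n = 3) and was called by DESeq2 (log2 fold change 1.16, adjusted p = 0.0017). Foxf1, Msx1 and, chosen after its values were seen, Hand2 were also higher by DESeq2, at log2 fold changes of 2.91, 2.80 and 2.34. Of 13 tested members of the lateral plate and cardiac mesoderm list, 11 were higher and 0 lower when adjusted over the list alone, 10 were higher by DESeq2, and 0 passed edgeR over all genes. The median was 1.16, with a camera adjusted p of 2.53e-08. With an estimated correlation the adjusted p was 0.318.

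In the blood and endothelium list, 11 of 20 members were tested. Of these, 9 were higher when adjusted over the list alone and 8 by DESeq2, with 0 past edgeR over all genes. The median log2 fold change was 1.51 (camera adjusted p = 6.22e-08, and adjusted p = 0.224 with an estimated correlation). Kdr, the VEGF receptor of early haemangiogenic mesoderm, was at 27.3, 1.52 and 2.97 CPM in WT and 76.9, 45.4 and 37.3 CPM in mutant libraries and passed neither test over all genes. Flt1, another VEGF receptor, averaged 95.5 and 102 CPM and differed by less than its spread. Gata2 and Etv2, transcription factors of blood and endothelium chosen after their values were seen, were called by DESeq2 at log2 fold changes of 1.51 and 2.52 (adjusted p = 1.53e-05 and 0.00872). Paraxial mesoderm genes had a median of 1.63, with 3 of 9 tested members higher when adjusted over the list alone, 1 by DESeq2 and 0 by edgeR over all genes (camera adjusted p = 0.00123, and adjusted p = 0.318 with an estimated correlation). Rspo3 and Dll3 averaged 4.03 and 5.52 CPM in WT and 26.8 and 17.2 CPM in mutant, without passing either test over all genes. Definitive endoderm genes had a median of 0.89 with 0 of 9 called by edgeR, adjusted over the list alone or by DESeq2 (camera adjusted p = 0.00304, and adjusted p = 0.398 with an estimated correlation). That median was 2.14 without WT replicate 1 and 0.51 without WT replicate 2. Trh averaged 11.98 and 56.65 CPM, and Clic6 21.8 and 16.6 CPM, with neither past a test.

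Posterior patterning genes belonged to the same side of the comparison. Of 21 Hox and Cdx list members, 9 were tested. Of these, 5 were higher when adjusted over the list alone and 5 by DESeq2, with 0 past edgeR over all genes. The median was 2.04 (camera adjusted p = 6.22e-08, and adjusted p = 0.296 with an estimated correlation). Without WT replicate 1 it was 3.83, but over 14 tested members, since the filter was rerun. Hoxd9 went from 0.867 ± 0.632 to 5.90 ± 1.16 CPM (SD, n = 3) and was called by DESeq2 (adjusted p = 6.11e-07). Cdx2, a posterior and trophoblast transcription factor, was fixed as a member of the trophoblast list and not of this one. It was at 7.23, 0.948 and 2.85 CPM in WT and 49.6, 26.3 and 19.9 CPM in mutant libraries (DESeq2 adjusted p = 0.0059, edgeR adjusted p = 0.095).

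Epithelial genes were lower and mesenchymal genes higher in mutant cells on the TMM scale. Of 19 epithelial state genes, 15 were lower and 1 higher when adjusted over the list alone, 13 were lower and 1 higher by DESeq2, and 0 passed edgeR over all genes. The list median was −0.50 with TMM and 0.06 with ERCC totals, and camera called it lower (adjusted p = 4.13e-07), which was lost with an estimated correlation (adjusted p = 0.382). Cdh1 (E-cadherin) and the splicing regulator Esrp1, chosen after their values were seen, were called lower by DESeq2 at log2 fold changes of −0.45 and −0.83, and Cdh1 turned to 0.15 with ERCC totals. The 1 gene higher was the keratin gene Krt8, at 1149 ± 88.0 and 1550 ± 164 CPM (SD, n = 3, DESeq2 adjusted p = 0.0132). Its partner Krt18 averaged 1169 and 1118 CPM and was not called. Whether copies of the keratin genes elsewhere in the genome share their reads was not examined, so their counts are uncertain.

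Among 12 tested mesenchymal state genes, 7 were higher and 0 lower when adjusted over the list alone, 5 were higher by DESeq2, and 0 passed edgeR over all genes (median 0.99, camera adjusted p = 2.15e-05, and adjusted p = 0.382 with an estimated correlation). Vim, the intermediate filament vimentin, went from 238 ± 98.4 to 512 ± 46.1 CPM (SD, n = 3), and Fn1, the matrix protein fibronectin, from 898 ± 156 to 1410 ± 322 CPM. DESeq2 called both (adjusted p = 0.000708 and 0.0153). Zeb2, a repressor of epithelial genes chosen after its values were seen, had a DESeq2 log2 fold change of 1.86 (adjusted p = 0.000274).

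Pluripotency lists were not called with all 6 libraries, and leaving out 1 library could change that. Naive pluripotency genes had a median of −0.35, with 1 of 14 lower when adjusted over the list alone, 2 lower by DESeq2 and 0 past edgeR over all genes (camera adjusted p = 0.148). Without mutant replicate 3 that list was called lower, at a median of −0.55 (camera adjusted p = 0.00158), while the median was −0.14 without mutant replicate 1 and −0.22 without mutant replicate 2. Core pluripotency and epiblast genes had a median of −0.17, with 0 of 14 called when adjusted over the list alone and 2 lower by DESeq2 (camera adjusted p = 0.272). This list was called lower without WT replicate 2, at −0.35 (camera adjusted p = 0.00187), and without mutant replicate 2, at −0.32 (camera adjusted p = 0.0285), while its median was −0.07 without mutant replicate 1 and −0.10 without WT replicate 3. Both medians with all libraries turned positive with ERCC totals, at 0.25 and 0.34. Nanog averaged 96.1 and 111 CPM, Dppa5a 154 and 109 CPM, Lin28a 495 and 568 CPM, and Pou5f1 (Oct4) 407 and 346 CPM, with none of them called by edgeR or DESeq2. Dppa4, chosen after its values were seen, went from 23.6 ± 6.19 to 7.42 ± 2.88 CPM (SD, n = 3) and was called lower by DESeq2 (adjusted p = 6.57e-06).

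Targets of BMP and WNT signalling had higher levels in mutant libraries. The BMP-induced genes Id1 and Id3 went from 68.3 ± 2.59 to 120 ± 22.9 CPM and from 74.9 ± 7.39 to 137 ± 25.1 CPM (SD, n = 3), and DESeq2 called both (adjusted p = 0.000101 and 6.18e-05). In the BMP list 4 of 6 tested members were higher when adjusted over the list alone and 4 by DESeq2 (median 0.84, camera adjusted p = 6.06e-05, and adjusted p = 0.318 with an estimated correlation). In the WNT list 5 of 10 were higher when adjusted over the list alone and 2 by DESeq2 (median 1.43, camera adjusted p = 0.00131, and adjusted p = 0.398 with an estimated correlation). Axin2, a feedback gene of WNT signalling, averaged 18.2 and 50.4 CPM (DESeq2 adjusted p = 0.0619), and Tcf7 averaged 128 and 111 CPM. The NODAL list had a median of 1.03 with 0 of 5 members called by edgeR, adjusted over the list alone or by DESeq2. Camera called it at adjusted p = 0.0476, which was 0.565 with an estimated correlation. The call was also lost without WT replicate 3 (median 0.82, camera adjusted p = 0.102) and without mutant replicate 3 (median 1.15, camera adjusted p = 0.081), and the median was 1.81 without WT replicate 1. Smad7 averaged 76.9 and 95.7 CPM and Skil 183 and 165 CPM. No member of these 3 lists passed edgeR over all genes.

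FGF and ERK readouts were split. In the ERK list 2 of 17 members were higher and 2 lower, both when adjusted over the list alone and by DESeq2, with 0 past edgeR over all genes (median −0.14 with TMM and 0.43 with ERCC totals, camera adjusted p = 0.792). That median was −0.08 without WT replicate 3, −0.09 without mutant replicate 3 and −0.23 without mutant replicate 1. The cell cycle gene Ccnd1 averaged 109 and 234 CPM and Myc, chosen after its values were seen, 22.2 and 48.4 CPM, both called by DESeq2 (adjusted p = 0.00265 and 0.00233), and Dusp6 averaged 148 and 120 CPM. Immediate early genes had a median of −0.52 with TMM and 0.08 with ERCC totals, with 0 of 13 called when adjusted over the list alone and 4 lower by DESeq2. Camera called the list lower (adjusted p = 0.000611, and adjusted p = 0.577 with an estimated correlation), and its median was −0.79 without mutant replicate 3. Fos averaged 611 and 464 CPM without a call, and Ccn1 averaged 1004 and 688 CPM (DESeq2 adjusted p = 0.0336).

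All 24 DNA replication genes had positive log2 fold changes, from 0.02 to 0.89, with 4 higher when adjusted over the list alone, 6 higher by DESeq2 and 0 past edgeR over all genes (median 0.46 with TMM and 0.96 with ERCC totals, camera adjusted p = 2.53e-08, and adjusted p = 0.469 with an estimated correlation). Pcna, the replication clamp, went from 231 ± 47.0 to 340 ± 28.4 CPM (SD, n = 3, DESeq2 adjusted p = 0.0149), Mcm7 averaged 226 and 304 CPM, and Tyms, thymidylate synthase, chosen after its values were seen, averaged 39.4 and 71.7 CPM (DESeq2 adjusted p = 0.00432). All 24 mitosis genes had negative log2 fold changes with TMM, from −0.51 to −0.02, while the list median of −0.29 became 0.33 with ERCC totals, where camera did not call it (adjusted p = 0.0632). Of them 12 were lower when adjusted over the list alone, 8 by DESeq2 and 0 by edgeR over all genes (camera adjusted p = 1.18e-06, and adjusted p = 0.382 with an estimated correlation). Aurkb, which encodes Aurora B and was chosen after its values were seen, was at 118 ± 2.32 and 87.8 ± 9.62 CPM (SD, n = 3), called lower by DESeq2 (log2 fold change −0.42, adjusted p = 0.0148) and at 0.16 with ERCC totals. Top2a averaged 913 and 796 CPM and Mki67 501 and 448 CPM, with neither called.

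Targets of p53 were lower with TMM, at a median of −0.59 that became 0.09 with ERCC totals and was −0.33 without WT replicate 2. Of 21 members, 2 were lower when adjusted over the list alone, 7 were lower by DESeq2 and 0 passed edgeR over all genes (camera adjusted p = 5.28e-06, and adjusted p = 0.565 with an estimated correlation). Trp53inp1 averaged 484 and 320 CPM (DESeq2 adjusted p = 0.0478), and Ccng1 averaged 658 and 506 CPM without a call. Among 16 apoptosis-promoting genes, 4 were lower and 0 higher when adjusted over the list alone and 3 were lower by DESeq2, with a median of 0.12 (camera adjusted p = 0.908) that was 0.18 without WT replicate 1 and 0.07 without WT replicate 2. Apaf1 averaged 172 and 138 CPM and Cycs 86.5 and 109 CPM, with neither called over all genes by edgeR or DESeq2, and Apaf1 was among the 4 lower over the list alone. Apoptosis-restraining genes had a median of −0.15 with TMM, −0.09 without mutant replicate 1 and 0.43 with ERCC totals, 0 of 10 were called when adjusted over the list alone or by DESeq2, and camera did not call the list (adjusted p = 0.299). Mcl1 averaged 407 and 332 CPM and Birc6 258 and 230 CPM. Cytosolic ribosomal protein genes, many of which share reads with pseudogenes, had a median of −0.20 with TMM and 0.44 with ERCC totals and 0 of 34 called members. Its TMM median was −0.30 without WT replicate 1 and −0.10 without WT replicate 2. Camera called that list lower (adjusted p = 0.000611), which was lost with an estimated correlation (adjusted p = 0.751) and with ERCC totals (adjusted p = 0.266). Rpl4 averaged 3226 and 2591 CPM and Rpsa 2202 and 1947 CPM.

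**Figure D3:**
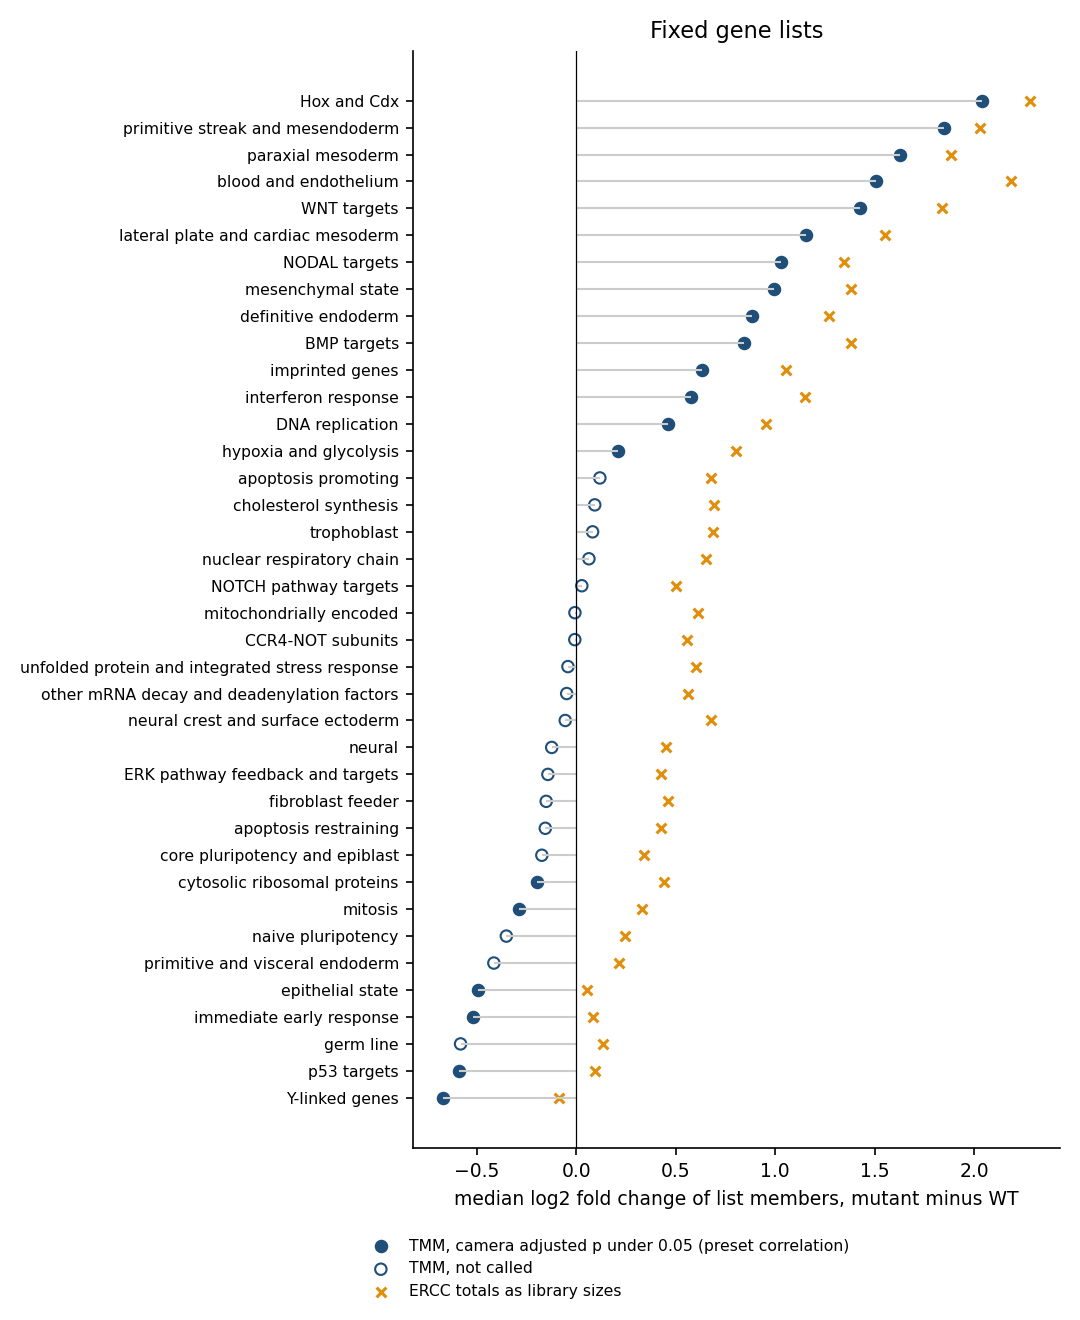
Median log2 fold change, mutant minus WT, of each of the 38 fixed lists, with TMM library sizes (circles, filled where camera with the preset correlation gave an adjusted p under 0.05) and with ERCC totals (crosses). Hox and Cdx and the primitive streak list lie highest at 2.04 and 1.85 with TMM, and lists below 0 with TMM mostly lie above 0 with ERCC totals, including epithelial state, which moves from −0.50 to 0.06.

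Across the 38 lists, camera with the preset correlation called 20, of which 14 were higher and 6 lower in mutant cells. With an estimated correlation 0 were called, and the smallest adjusted p was 0.224. Fry, which tests whether the genes of a list move on balance one way, called 3 lists (blood and endothelium, Hox and Cdx, and apoptosis-restraining genes, each at adjusted p = 0.0291).

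The ERCC spike-in share, which depends on the RNA recovered from a fixed number of cells, overlapped between the genotypes. On the CPM scale, over gene and ERCC counts together, it was 309, 857 and 462 in WT replicates 1 to 3 and 309, 248 and 438 in mutant replicates 1 to 3. The means were 542 ± 282 and 332 ± 96.7 (SD, n = 3), a mutant minus WT difference of −211 with an exact permutation p of 0.2, in a test that cannot go below 0.1 and leaves open whether the shares differ. Without WT replicate 2, whose share was the highest, the difference was −53.9. As the negative control, 0 of 20 tested ERCC species were called by edgeR with ERCC totals as library sizes, and 1 had an unadjusted p under 0.05. Scaling the species to their own total sets their median log2 fold change near 0. With TMM library sizes that median was −0.78 and still 0 of 23 species were called. The control therefore could not show a shift of that size. Because ERCC totals divide every gene count in a library, WT replicate 2 weighs on all values scaled by them.

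**Figure D4:**
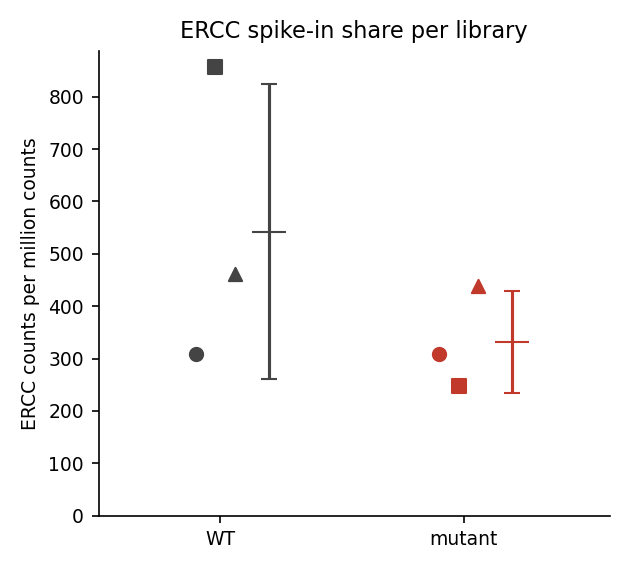
ERCC spike-in counts on the CPM scale, over gene and ERCC counts together, for each library, with WT in grey and mutant in red, circles, squares and triangles for replicates 1, 2 and 3, and bars for the group mean ± SD. WT replicate 2, at 857, lies above the other 5 libraries, which span 248 to 462.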

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

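An adjusted p under 0.1, the fit with bias-adjusted deviances and DESeq2 without each library were chosen after seeing the data. The count of 1 changed gene was also 1 with DESeq2 size factors, total counts, a mean CPM of at least 1, limma-voom, an adjusted p under 0.01, at least 2-fold and bias-adjusted deviances. It was 113 with ERCC totals (113 higher, 0 lower), 677 without a filter (322 higher, 355 lower), 840 at an adjusted p under 0.1 (353 higher, 487 lower) and 1667 by DESeq2 (733 higher, 934 lower). With the replicate number as a block it was 674 (309 higher, 365 lower). Pairing by number had no support from the deviations of the libraries from their group means, though 3 libraries per group cannot exclude it. Same-numbered libraries had correlations of 0.43, −0.17 and −0.07 between their deviations, and WT replicate 2 correlated best with mutant replicate 3 (0.48). Of the DESeq2 calls, 634 were also called without a filter and 613 with the block. Leaving out 1 library gave 0 to 2796 changed genes (0 to 1391 higher, 0 to 1405 lower), and 221 to 3386 by DESeq2, the highest without WT replicate 1 each time. The cause of these shifts was not tested. Leaving out a library leaves fewer samples, which does not account for the rise without WT replicate 1. That library was the WT library nearest to the mutant group on PC1, at 4.36 against −63.7 and −36.1 for WT replicates 2 and 3. Lists called fell from 20 to 0 with an estimated correlation and to 3 by fry, and were 18 to 25 under the other settings. The ERCC share difference kept its sign in all fits, from −327 without WT replicate 1 to −53.9 without WT replicate 2. In all fits 0 ERCC species were called, also with TMM library sizes, where their median log2 fold change was −0.78.

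Scaling by ERCC totals moved the median gene to 0.57, and by that construction small negative values changed sign. Among all 38 lists the medians that did were epithelial state 0.055, immediate early response 0.083, p53 targets 0.094, naive pluripotency 0.25, germ line 0.13, primitive and visceral endoderm 0.22, mitosis 0.33, core pluripotency 0.34, ERK 0.43, apoptosis-restraining 0.43, ribosomal proteins 0.44, neural 0.45, fibroblast feeder 0.46, CCR4-NOT 0.55, other mRNA decay 0.56, unfolded protein and integrated stress response 0.60, mitochondrially encoded 0.61, and neural crest and surface ectoderm 0.68. The genes that did were Trp53inp1 0.058, Dppa5a 0.069, Ccn1 0.091, Bst2 0.15, Cdh1 0.15, Aurkb 0.16, Fos 0.16, Clic6 0.24, Apaf1 0.25, Ccng1 0.31, Slc2a3 0.31, Cnot6l 0.34, Rpl4 0.34, Mcl1 0.36, Pou5f1 0.36, Eif2s3y 0.37, Dusp6 0.37, Mki67 0.37, Skil 0.41, H2-K1 0.41, Top2a 0.41, Birc6 0.43, Cnot8 0.45, Rpsa 0.45, Tcf7 0.45, Cnot1 0.47, Cnot4 0.53, Cnot7 0.55 and Krt18 0.58. With all libraries kept, the other sign changes among named genes and described lists were near 0: Cnot7 and the CCR4-NOT median were at 0.0096 without a filter, and Cnot7 at 0.044 with total counts. Leaving out 1 library gave ranges that crossed 0 for Cnot7 and the CCR4-NOT median (−0.047 to 0.025), Cnot4 (−0.15 to 0.0057), Krt18 (−0.17 to 0.16), Slc2a3 (−0.25 to 0.043), Clic6 (−0.62 to 0.079), Flt1 (−0.11 to 0.44) and Nanog (−0.19 to 0.80). The same held for 9 lists without a call: primitive and visceral endoderm (−0.73 to 0.38), fibroblast feeder (−0.49 to 0.16), neural crest and surface ectoderm (−0.21 to 0.16), neural (−0.16 to 0.18), mitochondrially encoded (−0.08 to 0.11), unfolded protein and integrated stress response (−0.07 to 0.11), trophoblast (−0.07 to 0.39), NOTCH targets (−0.05 to 0.23) and cholesterol synthesis (−0.02 to 0.15). Depth was even across libraries and limits mainly genes near the floor of 0.154 to 0.179 CPM.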

Other observations

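The tests of explanations in this part were chosen after the results were seen. Imprinted genes, expressed from 1 parental allele, were higher in mutant cells, by camera with the preset correlation. Of 22 tested, 9 were higher and 0 lower when adjusted over the list alone, 8 were higher by DESeq2 and 0 passed edgeR over all genes. The median log2 fold change was 0.63 (camera adjusted p = 4.34e-07, and adjusted p = 0.318 with an estimated correlation). The growth factor gene Igf2 went from 517 ± 210 to 1844 ± 402 CPM and Peg10 from 1232 ± 365 to 2617 ± 405 CPM (SD, n = 3), and the NOTCH-like ligand gene Dlk1, chosen after its values were seen, from 3.77 ± 1.94 to 16.9 ± 3.59 CPM. DESeq2 called these 3 genes (adjusted p = 2.79e-08, 6.93e-05 and 1.5e-07). Interferon response genes had a median of 0.58 with 3 of 15 higher both when adjusted over the list alone and by DESeq2 (camera adjusted p = 0.0229, and adjusted p = 0.382 with an estimated correlation), a camera call lost without WT replicate 3 (median 0.58, camera adjusted p = 0.0629) or mutant replicate 3 (median 0.55, camera adjusted p = 0.137). Isg15, chosen after its values were seen, averaged 3.02 CPM in WT and 14.2 CPM in mutant, and DESeq2 called it. The most abundant members H2-K1 and Bst2 averaged 157 and 162 CPM in WT and 129 and 113 CPM in mutant, with neither called. Hypoxia and glycolysis genes went both ways, with 6 of 23 higher and 1 lower both when adjusted over the list alone and by DESeq2 (median 0.21, and 0.34 without mutant replicate 1, camera adjusted p = 0.00891, with adjusted p = 0.382 with an estimated correlation and 0.0611 with ERCC totals). Ldha, lactate dehydrogenase, chosen after its values were seen, averaged 503 and 1106 CPM and was called higher by DESeq2 (adjusted p = 0.00231), Slc2a3 and Pkm averaged 3868 and 1621 CPM in WT against 3486 and 2443 CPM in mutant without a call, and Adm, which encodes adrenomedullin, was the 1 member lower.

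The rule for rises and falls, applied to DESeq2 after seeing the data, ranks only reported calls with a mean CPM of at least 5 and no overlap between groups. By it the largest log2 fold changes were Cdx2, Fgf3, Foxf1, Msx1, Sall3, Ccno, Fst and Col1a1 among rises and Adm, Aim2, Rgl3, Nupr1, Itgb4, Slc30a3, Tmem151a and Scn3b among falls. Col1a1, a collagen gene, was at 128, 29.3 and 31.2 CPM in WT and 356, 255 and 301 CPM in mutant libraries. Itgb4, an integrin of epithelial attachment, was at 25.5, 69.4 and 54.2 CPM in WT and 10.5, 12.7 and 14.7 CPM in mutant libraries, and Aim2, a DNA sensor, averaged 9.60 and 2.16 CPM. None of these 16 genes passed edgeR, where their adjusted p ranged from 0.0931 to 0.104. Of 4 Y-linked genes, which can share reads with X-linked copies, 3 were lower when adjusted over the list alone and 2 by DESeq2, with edgeR log2 fold changes of −0.80 for Ddx3y, −0.71 for Kdm5d, −0.63 for Uty and −0.25 for Eif2s3y, the last turning to 0.37 with ERCC totals (median −0.67, camera adjusted p = 0.0014, and adjusted p = 0.318 with an estimated correlation). Uty and Kdm5d were chosen after their values were seen. The other 12 lists were not called by camera, with adjusted p from 0.148 to 0.952 and medians from −0.58 to 0.09. They are other mRNA decay factors, primitive and visceral endoderm, trophoblast, neural, neural crest and surface ectoderm, germ line, fibroblast feeder, NOTCH targets, mitochondrially encoded genes, nuclear respiratory chain, unfolded protein and integrated stress response, and cholesterol synthesis. Camera called 4 of them when 1 library was left out. Primitive and visceral endoderm was lower without WT replicate 1 (median −0.73), WT replicate 2 (−0.44), mutant replicate 1 (−0.57) or mutant replicate 2 (−0.48), and had a median of 0.38 without WT replicate 3, where it was not called. Trophoblast was higher without WT replicate 1 (0.39), WT replicate 2 (0.33) or mutant replicate 2 (0.32), and cholesterol synthesis (0.15) and nuclear respiratory chain (0.09) were higher without WT replicate 2. With all libraries kept, camera called trophoblast higher with ERCC totals (median 0.69, adjusted p = 0.00123) and primitive and visceral endoderm lower without a filter (median −0.41, adjusted p = 0.0253).

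There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 1 edgeR call, the most of any (1 of 10 splits gave as many), and the highest of the other splits gave 0. By DESeq2 the real split gave 1667 and the highest other split gave 316, with 1 of 10 splits as large. That other split set WT replicate 1 with mutant replicates 1 and 2 and gave 2946 genes at an unadjusted edgeR p under 0.05. Camera with the preset correlation called 20 lists for the real split and up to 19 for the others, with 1 of 10 splits as large, so this test calls 12 to 19 lists for other groupings of these libraries too. All 10 splits called 0 ERCC species.

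All mutant libraries lay beyond all WT libraries on the leading expression axis, which also spread the libraries within each genotype. A smooth of GC content and transcript length explained 0.236% of the variance of the group difference over genes, which argues against that bias as the main source. With the primitive streak score of each library as a covariate, 853 genes had an unadjusted p under 0.05 in the real split against 1534 in the highest other split. Without the score the real split had 3910 such genes over all tested genes and that other split 259. The score lowered the count of the real split and raised that of the other. The other splits are thus not a like comparison, and these counts do not decide the question. Outside the primitive streak list, 3901 genes had an unadjusted p under 0.05 before. Over them the median absolute log2 fold change fell from 0.56 to 0.21 and the median SE stayed at 0.18. These genes were selected by that threshold in the same data, so some of the fall is built in. Part of the group difference may still follow a stage of differentiation that libraries of both genotypes share. A mutation that speeds up differentiation predicts the same values, and because the score itself differs between the groups the covariate takes up part of any genotype effect. Whether cultures were started or collected at different stages by chance, or the genotype sets the stage, stays open.

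Nudcd3 and Cnot3 did not follow the primitive streak score. With the same covariate their log2 fold changes were −1.16 (SE 0.11, edgeR adjusted p = 0.0279) and −0.85 (SE 0.11, edgeR adjusted p = 0.164). A stage difference measured by this score therefore does not account for either value. Stage differences that the score does not capture were not tested. The 20 tested neighbours of Nudcd3 on chromosome 11 had a median of 0.13, and those of Cnot3 on chromosome 7 a median of −0.10, and the lower quartiles of both sets, −0.06 and −0.37, lay above the value of the gene itself, which argues against a loss of the whole region. An effect of the CNOT3 substitutions, of the editing at the Cnot3 locus, or of a difference between the cell lines that is unrelated to the mutation is a candidate explanation for each, and none of these was tested. Reads over the edited codons were not analysed here.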
